A study of Rattus norvegicus with 20 samples.

How the data were processed

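The samples were cortical collecting ducts, the kidney tubule segment in which vasopressin sets water permeability, dissected by hand from 20 male Sprague-Dawley rats that were 5 weeks old. All rats carried a minipump with DDAVP, a vasopressin V2 receptor agonist, at 5 ng per hour. Per the labels, 10 rats received a water load of 50 mL per day in gelled food and 10 control rats received 25 mL per day, and ducts were taken after 1, 2 or 4 days. The groups held 3 control and 3 water-loaded rats at day 1, 4 and 4 at day 2, and 3 and 3 at day 4. Each library came from a separate rat. Per the labels' protocols, cDNA was made directly in the tubule lysate and amplified by a method written for single cells, then sheared and built into libraries.

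The deposited counts were whole numbers of reads per gene for 32545 Ensembl genes, 1 column per rat. Trimmomatic 0.32, STAR 2.4.0.1, SAMtools and HTSeq and the genome build rn6 are named in the submitters' processing notes, without settings; the gene annotation and the use of strand in counting are not given in the sources used here. The 5 summary lines that name no gene held 31.45% to 35.61% of the counts in a library. Most of these were reads that mapped to more than 1 place, 21.32% to 26.92%, and 0.53% to 1.26% were ambiguous between genes. These lines were left out of library sizes and tests. Values of genes with near-identical copies or retrocopies, such as Gapdh, Pgk1, tubulin and ribosomal protein genes, are therefore uncertain. Reads on genes numbered 33527913 to 74868598 per library (median 55672837), so that 1 count was worth 0.0134 to 0.0298 CPM, a count scaled to the size of its library, and the floor of 3 counts 0.0401 to 0.0895 CPM. Amplified reads without molecular identifiers are not independent molecules, so these floors cover counting error only. The FPKM values deposited by the authors were the same counts rescaled: in 13538 genes with at least 50 counts in 2 or more libraries, 0 had an implied length that varied between libraries by more than 0.1%. They were used only in alternatives. In 27 genes the symbol was a bare number, and these went unnamed. Gene positions were not used here, and the 0 Ensembl identifiers that matched the reference gene table gave no further names.

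Counts were tested with edgeR 4.0.16 in R 4.3.3, after filterByExpr on group left 14472 genes, with TMM factors. All 20 libraries entered 1 quasi-likelihood fit with robust dispersions and a mean per group, because groups of 3 or 4 share too little information alone. The contrasts were water load minus control at each day, their average with equal weight, the difference of the effect between days (F test), and the days among control rats (F test). Adjusted p is Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Group values are TMM-normalised CPM, mean ± SD over rats. Folds come from the fitted log2 difference. Over the average of days they need not equal the ratio of the means, and the SD there also spans the days. Aqp2 and Aqp3 were also tested by exact two-sided permutation of mean log2 CPM (prior count 2).

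Of 33 gene lists fixed from textbook knowledge, 31 had the 4 measured members needed for a test; the podocyte markers had 2 and the red blood cell markers 3. Of 619 list entries, 21 were not matched in the counts by symbol. Lists were tested with camera of limma 3.58.1 on log2 CPM, with a preset inter-gene correlation of 0.01, adjusted over the 31 lists of a contrast, and again with an estimated correlation and with fry. The median log2 difference over all genes on this scale was 0.002 at day 1, 0.061 at day 2, 0.148 at day 4 and 0.153 over the average. Members adjusted over the list alone are given beside those adjusted over all genes.

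The design, lists, alternatives and the rule for named genes were set before the data were examined. The rule named Aqp2, Aqp3, Aqp4, Avpr2, Scnn1a, Scnn1b and Scnn1g at every day. Of the genes called at a day it named those with the largest rise and fall and no overlap between the groups, and up to 2 called members per list. Where fewer than 10 genes were called, it named the 5 genes per direction with the smallest unadjusted p, given as values that did not pass. Over the average it named the 5 called genes per direction with the smallest adjusted p, and over the days in control rats the 6 called genes with the smallest adjusted p. Apart from the 7 fixed genes and list members, a named gene needed a mean of at least 10 CPM and a symbol that is not a locus name. List members below 0.05 when adjusted over the list alone, other list members given as examples, Avpr1a and the other called genes of the average were chosen after their values were seen. Not every called gene is reported here by name.

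Whether replicate numbers pair rats across treatments was checked from the correlation of deviations from the group means. At day 2 the same-numbered libraries correlated at 0.148, 0.147, 0.154 and 0.236, all over 0.1, and the libraries numbered 1 and 2 stood apart from those numbered 3 and 4 in both treatments. Differently numbered libraries within these sets correlated at 0.11, 0.123, 0.188 and 0.204, so the day 2 values follow the sets and do not show pairing. At day 1 the values were -0.054, -0.059 and 0.06, and at day 4 -0.004, -0.034 and -0.091. The labels say nothing of pairing. A fit with the number as a block was an alternative, and its value stands beside the results it changes. Other alternatives were the size factors and the tests of DESeq2 1.42.0, limma-voom with quality weights, limma on log2(FPKM + 1) or log2(FPKM + 0.1), other filters on low counts, non-robust dispersions, covariates for a proximal tubule score and for the number of detected genes, each day fitted alone, and each library left out in turn. Added after the data were seen were 2 day 1 libraries set aside, a term for the day 2 libraries numbered 3 and 4, a filter of at least 50 CPM on average, a fibroblast and pericyte score as a covariate over the control days, and the 2 libraries set aside together with a filter of 5 CPM in 3 libraries.

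The tests were checked on simulated counts with 200 changed genes, all with a mean of at least 10 CPM. Genes were drawn independently from negative binomial counts with the gene-wise dispersions that edgeR estimated from these data. At an 8-fold change edgeR recovered 28.8% of changed genes for the day 1 design, 51.5% for day 2, 39.4% for day 4 and 83.3% for the average; at 2-fold it recovered 0%, 0%, 1.5% and 22.4%. Unchanged genes made up 0% to 6.5% of its calls in these 4 designs, against 50.3% to 62.1% of the calls of DESeq2. The simulation used the dispersions of edgeR and had no library that stood apart and no grouping of the day 2 libraries. These shares may therefore not hold for the real data, and they do not rank the tools on them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.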

Results

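Gene expression was measured in microdissected cortical collecting ducts of rats under constant DDAVP, to ask what changes when a water load is added, the setting in which the kidney escapes from the antidiuretic action of vasopressin. Water-loaded and control rats were compared after 1, 2 and 4 days, with 3, 4 and 3 rats per treatment. Reads on genes came to 56.3 to 60.7 M per library in day 1 control rats and 44.5 to 55.1 M in day 1 water-loaded rats. They came to 60.2 to 74.9 and 43.0 to 64.0 M at day 2, and to 35.8 to 48.9 and 33.5 to 40.8 M at day 4, in the same order. Between 12665 and 15266 genes were detected per library. Libraries of 1 group correlated across genes at 0.76 to 0.92 (median 0.853), and the common biological coefficient of variation over all genes was 1.06. Many single genes therefore had to change much to stand out. Some abundant genes varied less, such as Hmx2, which was called at 1.89-fold over the average of days. Day 1 control 1 and day 1 water-loaded 2 stood apart from the other libraries, with 12665 and 12788 genes detected and TMM factors of 0.645 and 0.686. The proximal tubule markers had a mean of 7.50 log2 CPM in day 1 water-loaded 2, against -0.29 ± 1.15 (SD, n = 3) in day 1 control rats.

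The first comparison asked what the water load changed over the 3 days together. Aqp2 (ENSRNOG00000054378), the water channel that vasopressin moves to the apical membrane of principal cells, was 2.1-fold lower in water-loaded rats. It stood at 13370 ± 3746 CPM against 28840 ± 11930 CPM in controls (SD, n = 10 each). Its log2 difference was -1.07 (SE 0.19, adjusted p = 0.0262 by edgeR). Aqp3 (ENSRNOG00000009797), a water channel of the basolateral membrane of the same cells, was 3.02-fold lower. It stood at 1052 ± 380.3 against 3400 ± 1833 CPM (log2 difference -1.59, SE 0.215, adjusted p = 0.00229). Permuting treatments within days gave an exact two-sided p of 0.000143 for Aqp2 and of 7.14e-05 for Aqp3, the smallest that the 28000 arrangements can give. The call of Aqp2 was lost with the replicate number as a block (adjusted p = 0.185) and with the number of detected genes as a covariate (0.0935), in a range of 0.00035 to 0.185 over its alternatives. It was also lost without day 1 control 1 (0.0691), day 1 water-loaded 3 (0.0534), day 2 control 3 (0.0531), day 2 water-loaded 1 (0.0642) or 2 (0.0502), day 4 control 1 (0.0642) or 2 (0.0668), or day 4 water-loaded 1 (0.0729) or 2 (0.091). Its log2 difference without any 1 library stayed between -1.16 and -0.98.

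Other genes that fell over the days together were Eva1b (ENSRNOG00000024818), Hmx2 (ENSRNOG00000020638), Sfrp2 (ENSRNOG00000009465) and Snn (ENSRNOG00000058739). Hmx2, a homeobox transcription factor on the list of type B intercalated cell markers, was 1.89-fold lower, at 1149 ± 257.8 against 2178 ± 550.9 CPM (log2 difference -0.92, SE 0.12, adjusted p = 0.00202). Every water-loaded rat lay below every control rat. Eva1b was 4.31-fold lower, at 90.35 ± 44.77 against 382.1 ± 204.8 CPM (adjusted p = 0.00202). Sfrp2, a secreted Wnt-binding protein, was 17.2-fold lower, at 4.56 ± 4.408 against 107.5 ± 115.6 CPM. That fold averages log2 differences of -2.09, -3.84 and -6.40 at days 1, 2 and 4, and is not the ratio of these means. Control rats stood at 23.31, 74.26 and 235.9 CPM at these days, so their SD also spans a difference between days. Snn was 1.99-fold lower, at 612.7 ± 119.1 against 1280 ± 360.8 CPM. Neither Sfrp2 nor Snn overlapped between treatments, and both had an adjusted p of 0.0131. Tuba4a (ENSRNOG00000003597), an alpha tubulin, rose 2.12-fold, from 123.9 ± 42.46 to 261.8 ± 75.49 CPM (adjusted p = 0.0357). Pgk1 (ENSRNOG00000058249), a glycolytic enzyme, rose 1.77-fold, from 1265 ± 335.1 to 2326 ± 813.9 CPM (adjusted p = 0.0491). Snn lost its call with the block (0.185), the number of detected genes (0.0767), log2(FPKM + 0.1) (0.0549) and log2(FPKM + 1) without a filter (0.0939), in a range of 1.47e-05 to 0.185 over its alternatives. The log2 difference of Sfrp2 went from -4.11 to -4.90 without day 4 water-loaded 2. Sfrp2 lost its call with the number of detected genes (0.0825) and without day 4 water-loaded 1 (0.0536), in a range of 3.89e-11 to 0.0825. Tuba4a lost it with the block (0.0731), the proximal tubule score (0.0561), the number of detected genes (0.108) and the 2 day 1 libraries that stood apart set aside (0.0625). It also lost it without day 1 control 1, day 1 water-loaded 3, day 2 control 1 or 3, day 2 water-loaded 1, 2 or 4, day 4 control 1 or 2, or day 4 water-loaded 1 or 2. Its adjusted p without these was 0.0503 to 0.126, in a range of 3.97e-05 to 0.126 over its alternatives. Pgk1 lost it with the block (0.185), DESeq2 size factors (0.0568), the proximal tubule score (0.0642), the number of detected genes (0.151) and a term for the day 2 libraries numbered 3 and 4 (0.05003). Setting the 2 day 1 libraries aside ended it too (0.089, or 0.0728 with a filter of 5 CPM), as did leaving out any 1 library except day 1 water-loaded 1, day 2 control 4 and day 4 water-loaded 3 (0.054 to 0.146), in a range of 0.00168 to 0.185.

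**Figure D1:**
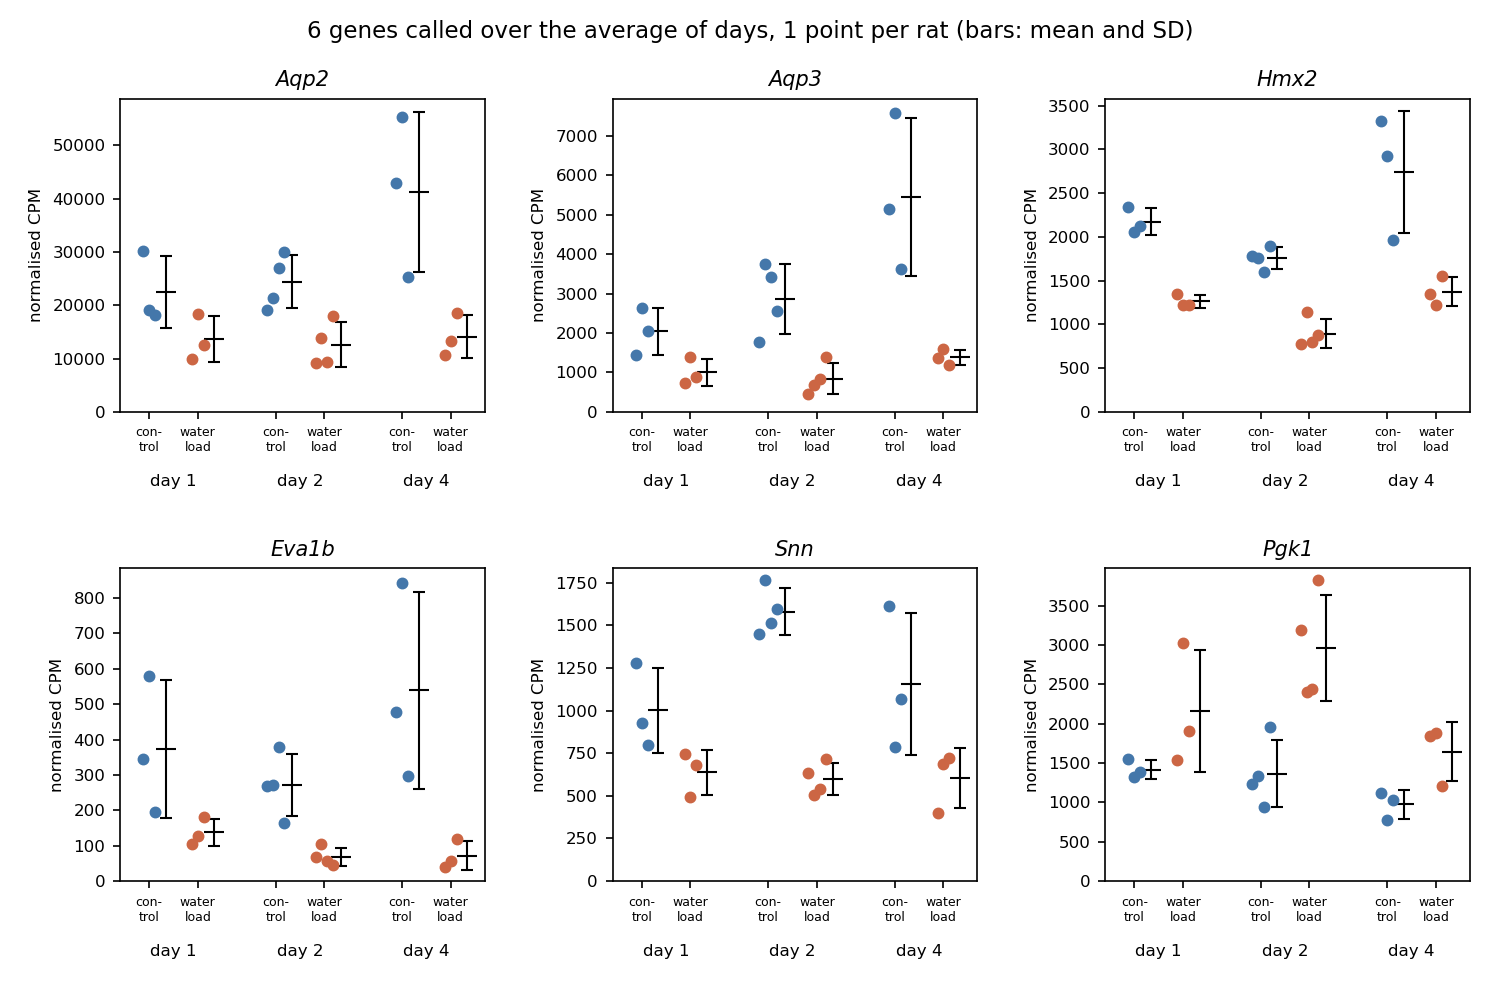
Normalised CPM (vertical axis, linear from 0) of Aqp2, Aqp3, Hmx2, Eva1b, Snn and Pgk1 in each rat, by day and treatment, with the mean and SD beside the points. Aqp2 was 13370 CPM on average in the 10 water-loaded rats and 28840 CPM in the 10 control rats.

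In all, 23 genes were called over the average, 11 higher and 12 lower, of 1950 with an unadjusted p under 0.05 (1074 higher, 876 lower), where 724 would be expected by chance. The other genes that fell were Btc, Vasn, Lmo4, Auh, Mrps6 and Avpr1a. Avpr1a, the gene of the V1a receptor, stood at 136.2 ± 39.83 against 243.4 ± 70.64 CPM (adjusted p = 0.0482). The call of Avpr1a was lost with the block (0.233), DESeq2 size factors (0.0568), the proximal tubule score (0.0573) and the number of detected genes (0.0935). It was lost on log2(FPKM + 1) (0.173, or 0.213 without a filter) and log2(FPKM + 0.1) (0.149), with no filter (0.0658) or one of 50 CPM (0.0588), and with the 2 day 1 libraries set aside (0.0894, or 0.0822 with a filter of 5 CPM). It was also lost without any 1 library except day 1 control 3, day 1 water-loaded 1, day 4 control 3 and day 4 water-loaded 3 (0.0533 to 0.144). The other genes that rose, among them Kctd21, Kif22, Cnih2, Mad2l1, Uhrf1, Knstrn, Cdca7 and Il34, had means under 10 CPM. Il34 did not rise at every day, with log2 differences of 9.94, -0.07 and 0.97 at days 1, 2 and 4. Aqp4, Avpr2, Scnn1a, Scnn1b and Scnn1g were not called, with log2 differences of -0.01, -0.28, -0.15, -0.03 and -0.09. With the block 5 genes were called. Without 1 library the count was 6 (day 4 control 1 or day 4 water-loaded 1) or 7 (day 1 control 1, day 2 water-loaded 1 or 2, day 4 water-loaded 2). It was 8 (day 1 control 2, day 2 control 3), 9 (day 2 water-loaded 4, day 4 control 2) or 10 (day 2 water-loaded 3), and 11 (day 1 water-loaded 3, day 2 control 1), 15 (day 2 control 2) or 37 (day 1 control 3).

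Of the 31 gene lists, 3 rose and 4 fell over the average, and none of these calls held with an estimated correlation. The principal cell markers fell, with 9 of 11 members lower and a median log2 difference of -0.27 (adjusted p = 0.000154; adjusted p = 0.168 with an estimated correlation). Without day 4 control 1 their median was -0.18. Aqp2 and Aqp3 were called over all genes, and 5 members when adjusted over the list alone. These were the same 2 with Npnt at -0.91 (SE 0.28), Gata3 at -0.62 (SE 0.21) and Fxyd4 at -0.62 (SE 0.24). Vasopressin signalling and water transport fell, with 18 of 27 members lower and a median of -0.33 (adjusted p = 0.00387; adjusted p = 0.0662 with an estimated correlation). Without day 1 control 1 its median was -0.195. Aqp2, Aqp3 and Avpr1a were the 3 members called over all genes and when adjusted over the list alone. This list and the principal cell markers share Aqp2, Aqp3, Aqp4, Avpr2 and Gata3, so their falls, here and at days 2 and 4, are not independent results. The cell cycle genes rose, all 24 higher with a median of 1.18 (adjusted p = 7.74e-06; adjusted p = 0.168 with an estimated correlation). When adjusted over the list alone 0 were called. The immediate-early genes fell, 18 of 19 lower with a median of -0.62 (adjusted p = 1.16e-05; adjusted p = 0.464 with an estimated correlation). Their median was -0.39 without day 1 control 1, -1.10 without day 1 control 3 and -0.41 without day 1 water-loaded 1. When adjusted over the list alone 2 were called, Ier3 at -1.22 (SE 0.33) and Zfp36 at -1.39 (SE 0.39).

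The immune cell markers, all 12 higher with a median of 1.29, rose too (adjusted p = 0.0227 or, with an estimated correlation, adjusted p = 0.503). This call was lost without day 1 control 1 (median 0.84, adjusted p = 0.0619), day 1 water-loaded 1 (0.059) or day 2 control 1 (0.0586), and with the 2 day 1 libraries that stood apart set aside (0.194). Cholesterol synthesis rose, 16 of 21 higher with a median of 0.70 (adjusted p = 0.0399; adjusted p = 0.191 with an estimated correlation). Insig1, which retains the sterol sensor in the endoplasmic reticulum, was at 1.30 (SE 0.36), the 1 member called when adjusted over the list alone. The call of the cholesterol synthesis list was lost with the block (0.0706), the proximal tubule score (0.0561) and a term for the day 2 libraries numbered 3 and 4 (0.0515). It was also lost without day 1 control 3, day 1 water-loaded 2 or 3, day 2 control 4, day 2 water-loaded 1, 2 or 4, day 4 control 2, or day 4 water-loaded 1 or 3. Its adjusted p without these was 0.0531 to 0.109. The unfolded protein and integrated stress response fell, 15 of 20 lower with a median of -0.31 (adjusted p = 0.0235; adjusted p = 0.354 with an estimated correlation). Manf, at -0.90 (SE 0.23), was the 1 member called when adjusted over the list alone. The call of the unfolded protein list was lost with the block (0.0523) and without day 1 control 2 (0.0834), day 1 water-loaded 1 (0.0934), day 2 control 2 (0.0663) or day 4 control 2 (0.0943). The median of that list was -0.13 without day 1 control 1 and -0.19 without day 1 water-loaded 2. The other 24 lists were not called, with adjusted p from 0.109 to 0.94. Among them, sodium and potassium transport had 10 members higher and 11 lower and a median of -0.01.

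After 1 day of water load no single gene passed the test. Aqp2 stood at 13610 ± 4291 CPM in water-loaded and 22430 ± 6717 CPM in control rats (SD, n = 3 each), a log2 difference of -0.72 (SE 0.34). Aqp3 stood at 1006 ± 345.4 and 2049 ± 595.2 CPM, a difference of -1.03 (SE 0.38). The exact permutation p was 0.2 for Aqp2 and 0.1 for Aqp3, the smallest that 3 against 3 rats can give. The genes with the smallest unadjusted p in the upward direction were Galnt10, at 24.47 ± 20.22 CPM in water-loaded and 0.0238 CPM in control rats, Mlph, at 32.58 and 0.101 CPM, and Tchp, at 20.13 and 0.337 CPM. With them were Nop56, at 158.1 ± 117 and 25.67 ± 12.29 CPM, and Lpxn, at 0.0184, 47.7 and 20.29 CPM in the 3 water-loaded rats against 0 counts in the control libraries. In the downward direction they were Slc2a4, at 0.0195 CPM against 56.2 ± 77.43 CPM, Foxp1, at 11.39 ± 5.503 against 99.39 ± 98.01 CPM, Pxmp2, at 10.06 ± 5.08 against 84.56 ± 64.9 CPM, P3h2, at 25.01 ± 7.154 against 102.1 ± 38.85 CPM, and Wfdc1. The log2 difference of Foxp1 went from -3.12 to -1.92 without day 1 control 1, and that of Pxmp2 from -3.07 to -2.26. Without any 1 library the log2 difference of Galnt10 was 8.96 to 11.02 (9.81 with all), that of Mlph 6.41 to 9.96 (8.25), that of Tchp 5.13 to 7.09 (5.87) and that of Nop56 1.83 to 2.975 (2.62). By edgeR 0 genes were called, 2254 had an unadjusted p under 0.05 (1244 higher, 1010 lower) and the smallest adjusted p was 0.164. DESeq2 called 1126 and limma-voom 0. Without day 1 control 3 edgeR called 9 genes, and 1 without day 1 water-loaded 1 or 2.

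Among the lists at day 1, the proximal tubule markers rose, 16 of 17 higher with a median of 2.90 (adjusted p = 0.00242; adjusted p = 0.794 with an estimated correlation). When adjusted over the list alone 5 were called, Lrp2, Pck1, Slc5a2, Slc22a8 and Slc22a12. The median of the list was 0.31 without day 1 water-loaded 2 (adjusted p = 0.971) and 4.95 without day 1 water-loaded 1. The immediate-early genes fell, 19 of 19 lower with a median of -0.88 (adjusted p = 0.00573; adjusted p = 0.794 with an estimated correlation), with 0 called when adjusted over the list alone. The call was lost without day 1 control 1 (median -0.04, adjusted p = 0.827) or day 1 water-loaded 1 (median -0.41, adjusted p = 0.572). Their median was -0.38 without day 1 control 2, -1.81 without day 1 control 3 and -1.35 without day 1 water-loaded 2. The proteasome genes fell, 26 of 31 lower with a median of -0.40 (adjusted p = 0.0214; adjusted p = 0.794 with an estimated correlation). Psmd13, at -1.15 (SE 0.31), was the 1 member called when adjusted over the list alone. Without day 1 control 1 (median -0.18, adjusted p = 0.41) or day 1 water-loaded 1 (0.0761) the call of the proteasome list was lost. With the 2 day 1 libraries that stood apart set aside, all 3 were lost, with adjusted p of 0.587, 0.187 and 0.633. The count of 3 lists became 1 without day 1 control 1 or day 1 water-loaded 1, 5 without day 1 control 2, 7 without day 1 control 3 and 6 without day 1 water-loaded 2.

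After 2 days the cell cycle genes stood out. They rose, 24 of 24 higher in water-loaded rats with a median log2 difference of 2.16 (adjusted p = 7.7e-13; adjusted p = 0.0378 with an estimated correlation). This was the 1 list call of any day that held with an estimated correlation. Their mean was 4.83 ± 0.31 log2 CPM in water-loaded and 2.46 ± 0.40 in control rats (SD, n = 4 each). Mki67, a marker of dividing cells, stood at 39.49 ± 24.54 against 4.01 ± 4.649 CPM, Ccnd1, a cyclin of the G1 phase, at 96.31 ± 34.75 against 44.17 ± 11.43 CPM, and Plk1, a mitotic kinase, at a log2 difference of 3.21. None of the 24 was called when adjusted over the list alone (smallest adjusted p 0.186). In 8 every water-loaded rat lay above every control rat, where chance gives 2.86% in both directions together. Libraries numbered 1 and 2 gave a median of 2.28 (22 of 24 higher) and those numbered 3 and 4 one of 1.83 (24 of 24). The immune cell markers, with a median of 0.55, were not called at this day. Nor were the fibroblast and pericyte markers, at 1.35 ± 0.97 log2 CPM in water-loaded and 0.02 ± 1.27 in control rats with all 7 higher (adjusted p = 0.118), or the endothelial markers, at 4.45 ± 0.96 and 3.38 ± 2.26 with 8 of 9 higher (adjusted p = 0.24).

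Aqp2 stood at 12620 ± 4245 CPM in water-loaded and 24370 ± 4969 CPM in control rats at day 2 (SD, n = 4 each), a log2 difference of -0.95 (SE 0.29). Aqp3 stood at 837.9 ± 394 and 2873 ± 885.7 CPM, a difference of -1.78 (SE 0.34). Both had an exact permutation p of 0.0286, the smallest that 4 against 4 rats can give. Within the libraries numbered 1 and 2 the differences were -0.84 for Aqp2 and -2.21 for Aqp3, and within those numbered 3 and 4 -1.14 and -1.46. The smallest unadjusted p in the upward direction belonged to Tubb5, a beta tubulin, at 548.4 ± 142.8 against 147.9 ± 37.61 CPM, Pgk1, at 2964 ± 675.4 against 1367 ± 429.3 CPM, and Tubb4b, with a log2 difference of 1.06. With them were Ankle1, at 28.92 against 0.257 CPM, and Acta1, at 0.0923, 50.05, 2.031 and 33.23 CPM in the 4 water-loaded rats against 0 counts in the control libraries. In the downward direction they were Aqp3, Snn, at 599.8 ± 95.79 against 1582 ± 137.6 CPM, Hmx2, at 895 ± 168 against 1758 ± 124.8 CPM, Btc, at 36.28 against 238.1 CPM, and Vasn, at 47.91 against 219 CPM. None passed: by edgeR 0 genes were called, 757 had an unadjusted p under 0.05 (400 higher, 357 lower) and the smallest adjusted p was 0.195. DESeq2 called 77 and limma-voom 6.

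Of the other lists at day 2, 4 rose and 6 fell, and none of these held with an estimated correlation. By fry, vasopressin signalling was the 1 of these 10 called (adjusted p = 0.0475). Nuclear-encoded oxidative phosphorylation rose, 37 of 39 higher with a median of 0.46 (adjusted p = 1.56e-05; adjusted p = 0.312 with an estimated correlation), with 0 called when adjusted over the list alone. Without day 2 control 3 its median was 0.24. Glycolysis rose, 15 of 18 higher with a median of 0.495 (adjusted p = 0.00245; adjusted p = 0.211 with an estimated correlation). When adjusted over the list alone 3 members were called, Pgk1, Gapdh, at 1327 ± 276.5 against 676.6 ± 277.5 CPM, and in the other direction the glucose transporter Slc2a1, at 106.1 ± 44.02 against 251.7 ± 73.25 CPM. Without day 2 control 3 the call of the glycolysis list was lost (0.0519). The shared intercalated cell markers rose, 7 of 9 higher with a median of 0.54 (adjusted p = 0.0264; adjusted p = 0.312 with an estimated correlation). When adjusted over the list alone 2 proton pump subunits were called, Atp6v0a4, at 1890 ± 314.7 against 1294 ± 173.9 CPM, and Atp6v1b1, at 2184 ± 216 against 1391 ± 278.6 CPM. The block (0.0577) ended the call of the shared intercalated list, as did leaving out day 2 control 3 (0.323) or day 2 water-loaded 4 (0.0773). Cholesterol synthesis rose, 18 of 21 higher with a median of 0.83 (adjusted p = 0.0229; adjusted p = 0.125 with an estimated correlation), with 0 called when adjusted over the list alone. It was lost without day 2 control 3 (0.0721) or 4 (0.089) or day 2 water-loaded 1 (0.0764) or 4 (0.0616).

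The principal cell markers fell at day 2, 9 of 11 lower with a median of -0.42 (adjusted p = 0.000665; adjusted p = 0.125 with an estimated correlation). Aqp3 (0.000478) and Aqp2 (0.0221) were called when adjusted over the list alone. Vasopressin signalling and water transport fell, 17 of 27 lower with a median of -0.32 (adjusted p = 0.00762; adjusted p = 0.0757 with an estimated correlation), and without day 2 control 2 its median was -0.19. Aqp3 was the 1 member called when adjusted over the list alone. Insulin and IGF signalling and mTOR fell, 15 of 24 lower with a median of -0.22 (adjusted p = 0.0229; adjusted p = 0.085 with an estimated correlation). It was lost without day 2 control 2 (median -0.06, adjusted p = 0.119) or day 2 water-loaded 4 (0.102), and its median was -0.39 without day 2 control 3, -0.37 without day 2 water-loaded 2 and -0.36 without day 2 water-loaded 3. The immediate-early genes fell, 16 of 19 lower with a median of -0.63 (adjusted p = 0.00383; adjusted p = 0.42 with an estimated correlation). This was lost without day 2 control 2 (median -0.39, adjusted p = 0.0568) or day 2 water-loaded 4 (0.0564). In the last 2 lists 0 were called when adjusted over the list alone. Markers of 2 other tubule segments fell as well, while those of the distal convoluted and connecting tubule were not called (5 of 8 higher, median 0.03, adjusted p = 0.384). Of the proximal tubule markers 15 of 17 were lower with a median of -2.06 (adjusted p = 1.56e-05; adjusted p = 0.312 with an estimated correlation). Without day 2 control 1 their median was -1.12. Of the thick ascending limb markers 6 of 6 were lower, with a median of -1.58 (adjusted p = 0.00383; adjusted p = 0.085 with an estimated correlation). When adjusted over the list alone 4 and 1 of these were called. The proximal tubule markers averaged 4.90 log2 CPM in day 2 control 1, and -0.11 ± 0.25 (SD, n = 4) in day 2 water-loaded rats. With the proximal tubule score as a covariate the calls of vasopressin signalling (0.187), insulin and IGF signalling (0.0877) and the immediate-early genes (0.22) were lost, with medians of -0.25, -0.60 and -0.43.

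**Figure D2:**
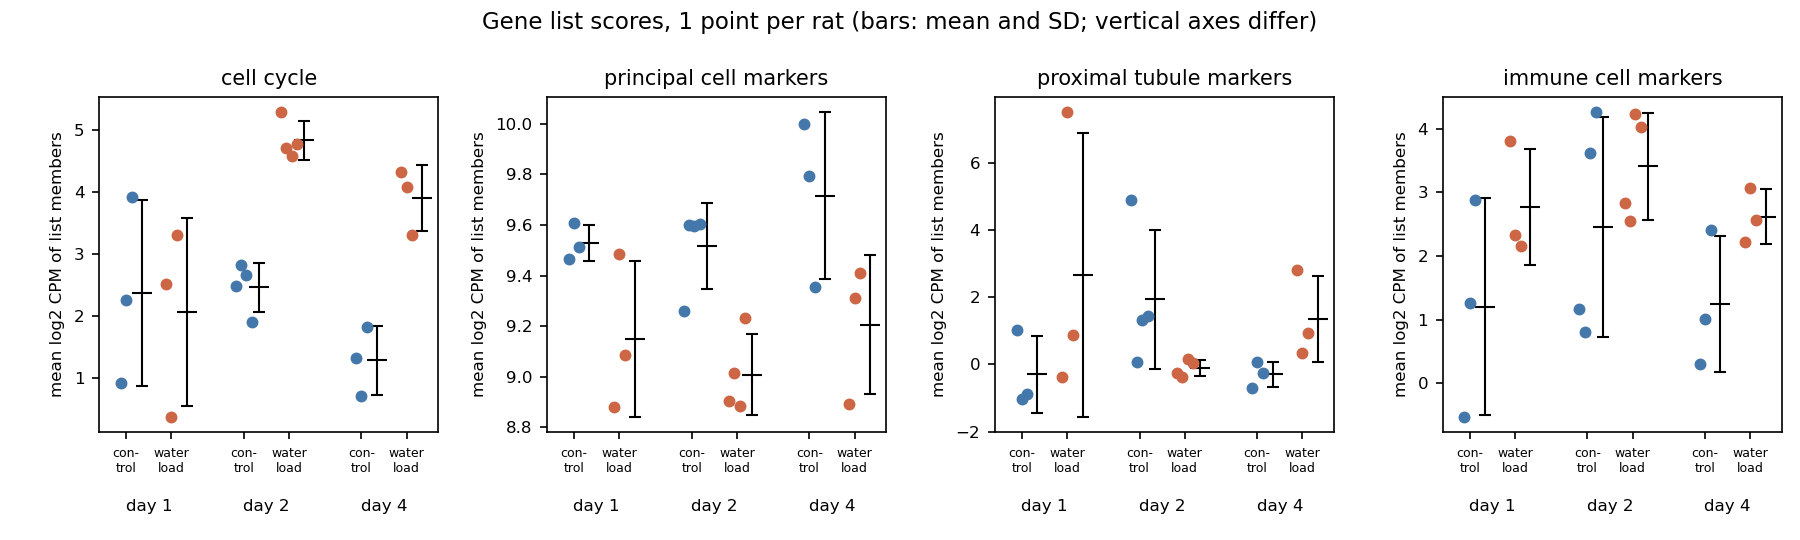
Mean log2 CPM over the members of 4 gene lists (vertical axes, which differ between panels) in each rat, by day and treatment, with the mean and SD beside the points. The cell cycle mean was 4.83 in water-loaded and 2.46 in control rats at day 2, and the proximal tubule mean reached 7.50 in 1 water-loaded rat of day 1.

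After 4 days Aqp2 stood at 14130 ± 3952 CPM in water-loaded and 41210 ± 15070 CPM in control rats (SD, n = 3 each), a log2 difference of -1.54 (SE 0.34). Aqp3 stood at 1385 ± 192.7 and 5452 ± 1996 CPM, a difference of -1.98 (SE 0.39). Both had an exact permutation p of 0.1, the smallest that 3 against 3 rats can give. The other genes with the smallest unadjusted p in the downward direction were Eva1b, at 71.92 ± 40.75 against 539.3 ± 278.5 CPM, Sfrp2, at 2.794 ± 3.933 against 235.9 ± 146 CPM, and Hmx2, at 1373 ± 165.5 against 2742 ± 699.7 CPM. In the upward direction they were Insig1, at 26.19 ± 8.46 against 4.928 ± 3.594 CPM, and Tuba4a, Papss1, Huwe1 and Psip1, with log2 differences of 1.21, 1.09, 1.85 and 3.83. Without day 4 control 1, at 4.429 CPM against 0.1234 and 0.4978 CPM in the other 2, that of Psip1 was 6.24. The log2 difference of Sfrp2 was -6.40, and -8.80 to -5.86 without any 1 library, with its water-loaded rats at 0.247 to 7.324 CPM. None passed: by edgeR 0 genes were called, 1045 had an unadjusted p under 0.05 (724 higher, 321 lower) and the smallest adjusted p was 0.234. DESeq2 called 319 and limma-voom 8.

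At day 4 each water-loaded library had more genes detected (14279 to 14482) than each control library (13071 to 13804). The cell cycle genes rose at day 4 too, 22 of 24 higher with a median of 2.83 (adjusted p = 2.14e-06; adjusted p = 0.196 with an estimated correlation), with 0 called when adjusted over the list alone. Their mean was 3.91 ± 0.53 log2 CPM in water-loaded and 1.28 ± 0.56 in control rats (SD, n = 3 each). In 10 of them every water-loaded rat lay above every control rat, where chance gives 10% in both directions together. The fibroblast and pericyte markers rose, 7 of 7 higher with a median of 3.32 (adjusted p = 0.00217; adjusted p = 0.223 with an estimated correlation). Pdgfrb, at 3.756 against 0.0164 CPM, and Col1a1, at 2.789 against 0.0287 CPM, were called when adjusted over the list alone, both below the floor of 3 counts in control rats. The median of the list was 1.54 without day 4 control 1 and 1.59 without day 4 water-loaded 2. It was 2.18 to 2.19 without day 1 control 2 or 3 or any 1 of the day 1 water-loaded libraries. The principal cell markers fell, 9 of 11 lower with a median of -0.28 (adjusted p = 0.00291; adjusted p = 0.223 with an estimated correlation). Aqp3, Aqp2 and Gata3, at 226.3 ± 91.85 against 506.7 ± 162.1 CPM, were called when adjusted over the list alone. The call of the principal cell list was lost without day 4 control 1 (0.0668) or day 4 water-loaded 1 (median -0.02, adjusted p = 0.0745). The median of that list was -0.18 without day 4 control 2, -0.60 without day 4 control 3 and -0.48 without day 4 water-loaded 3. Vasopressin signalling and water transport fell, 16 of 27 lower with a median of -0.43 (adjusted p = 0.00291; adjusted p = 0.0563 with an estimated correlation), and without day 4 control 2 its median was -0.29. Aqp3 and Aqp2 were called when adjusted over the list alone. The immediate-early genes fell, 15 of 19 lower with a median of -0.62 (adjusted p = 0.0263; adjusted p = 0.756 with an estimated correlation), with 0 called when adjusted over the list alone. They lost the call without day 4 control 2 (0.176) or day 4 water-loaded 1 (median -0.17, adjusted p = 0.401). The count of 5 lists became 8 without day 2 water-loaded 4 and 9 without day 4 water-loaded 2.

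**Figure D3:**
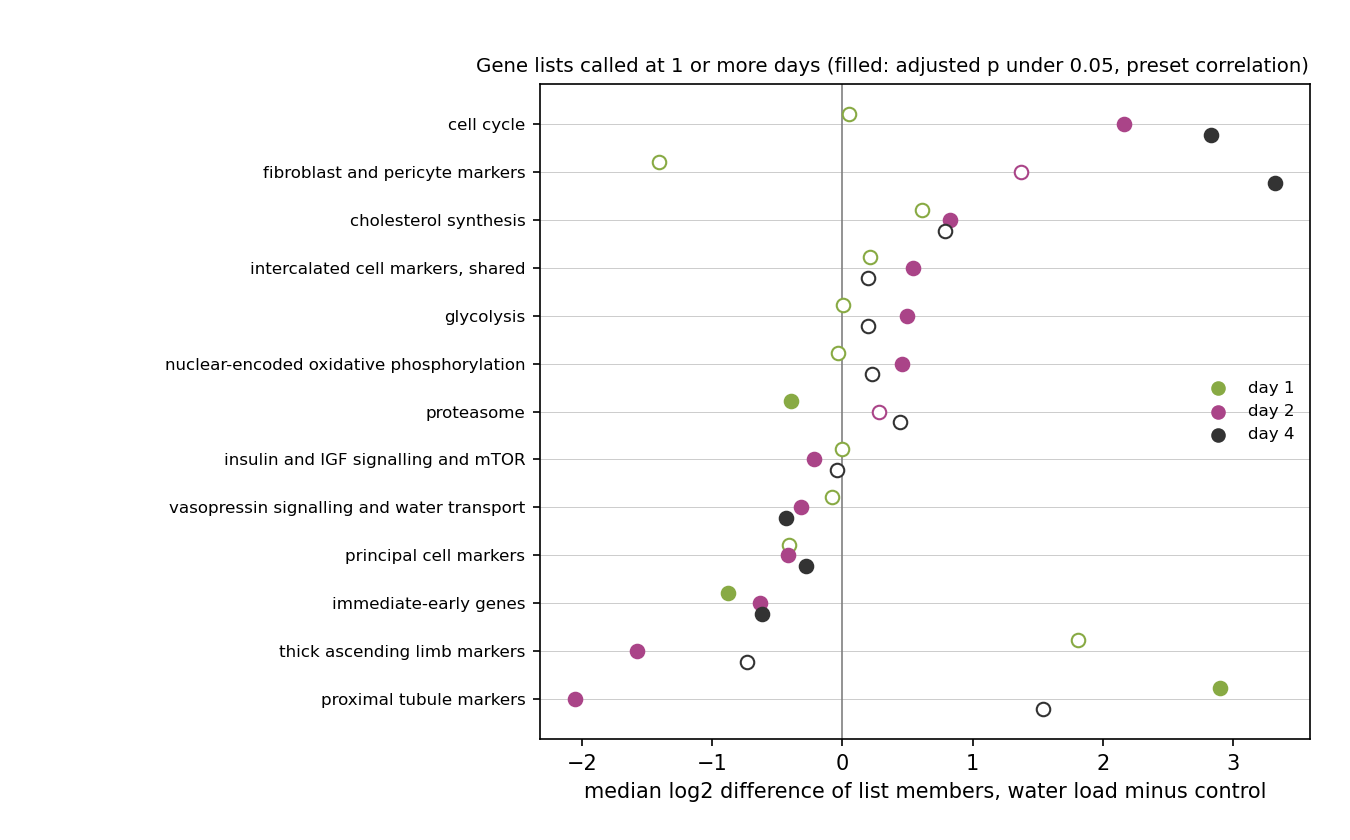
Median log2 difference between water-loaded and control rats (horizontal axis) of each gene list called at 1 or more days, with 1 point per day, filled where the adjusted p with the preset correlation was under 0.05. The cell cycle list stood at 0.05 at day 1, 2.16 at day 2 and 2.83 at day 4. The proximal tubule list stood at 2.90 at day 1 and -2.06 at day 2.

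Whether the effect of water load differed between days was tested directly. The log2 difference of Aqp2 was -0.72, -0.95 and -1.54 and that of Aqp3 -1.03, -1.78 and -1.98 at days 1, 2 and 4, and neither was called as differing. By edgeR 0 genes were called, 1239 had an unadjusted p under 0.05, and the smallest adjusted p was 0.43. DESeq2 called 193 and limma-voom 2. Without day 1 control 3 edgeR called 3 genes. Across the 14472 genes, which are not independent replicates, log2 differences correlated at -0.035 between days 1 and 2, 0.053 between days 1 and 4 and 0.149 between days 2 and 4, and 50.5%, 50.9% and 58.2% of genes had the same sign.

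Among control rats, 355 genes changed between days, 99 higher and 255 lower at day 4 than at day 1, and in 338 days 2 and 4 lay on the same side of day 1. Diras3 (ENSRNOG00000033736), a small GTPase, fell from 344.8 ± 82.81 CPM at day 1 (SD, n = 3) to 14.65 ± 2.118 at day 2 (n = 4) and 17.28 ± 4.913 at day 4 (n = 3), with an adjusted p of 0.00102 by edgeR. Clta (ENSRNOG00000014635), a clathrin light chain, fell from 1145 ± 235.7 to 91.04 ± 36.69 and 85.85 ± 21.34 CPM, with the same adjusted p. Eif3f, Ppp1cc and Suclg1 fell as well, from 1195, 536.1 and 1404 CPM at day 1 to 98.07, 117.8 and 308.9 CPM at day 4. Ssr3 rose from 20.31 ± 7.548 to 301.6 ± 120.2 and 252.6 ± 103.9 CPM. These 4 each had an adjusted p of 0.00194. Each day was also a separate set of rats and libraries, so time and any batch of libraries cannot be told apart in these values. The fibroblast and pericyte markers had a mean of 1.08 ± 2.52 log2 CPM in control rats at day 1 (SD, n = 3), 0.02 ± 1.27 at day 2 (n = 4) and -2.26 ± 0.93 at day 4 (n = 3). In day 1 control 1 they stood at 3.99, against -0.36 and -0.40 in the other 2. The endothelial markers stood at 4.02 there, against 1.13 and 3.23 in the other 2 and up to 5.49 in day 2 control rats. Eln, Cnn1, Myh11, Vim, Tagln, Des and Col1a1, chosen after their values were seen, were among the called genes that were lower at day 4. With the fibroblast and pericyte score as a covariate, added after the data were seen, 47 genes were called, 40 of them among the 355. Without day 1 control 1, 39 of the 355 were called again. The count was 43 without day 1 control 1, 548 without day 1 control 3, 563 without day 1 water-loaded 2, 231 without day 2 control 4, 72 without day 4 control 1 and 123 without day 4 control 2.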

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

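The test of immune markers against the cell cycle genes, both counts of splits with the smallest p of any list, and the tests of batch, of both scores and of the water-loaded rats on the control time course were chosen after the results were seen, as were the alternatives that set libraries aside.

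The cell cycle list was 2.16 log2 units higher at day 2, and of the 35 splits of the 8 libraries 1, the real one, gave a camera p as small as 2.48e-14, and the smallest of the others was 5.35e-09. The list was the one with the smallest p of 31, and 4 of the 35 splits gave some list a p as small: the real one, the split by libraries numbered 1 and 2 against 3 and 4 (9.62e-25), and 2 that put 3 libraries of one of these sets against 3 of the other; of the 18 splits that balance the numbers 1, the real one, did, the smallest other being 1.38e-09, and 18 are too few for a share under 0.05. The list's median lay at percentile 100 of 10000 lists matched on mean expression, whose highest median was 1.07. This argues against a general gain in detected genes. Such a gain was small at day 2, with 13322 to 15236 genes in control and 13651 to 15266 in water-loaded libraries. At day 4, where detected genes did not overlap between treatments, the percentile was also 100 and the highest matched median 1.54. Matched lists need not move together as cell cycle genes may, so this percentile does not measure chance. Immune markers had a median of 0.55 (interval over genes 0.016 to 1.61), below the cell cycle median. That interval covers the spread of genes and not of rats. More division among immune cells need not raise these markers, so this does not decide on dividing immune cells. The immune marker mean in libraries numbered 1 and 2 was 1.16 and 0.80 log2 CPM in control and 2.84 and 2.55 in water-loaded rats. In those numbered 3 and 4 it was 3.61 and 4.255 against 4.23 and 4.03. The cell cycle list was also higher at day 4, in separate rats, with a median of 2.83. Its camera adjusted p there was 2.14e-06, or 0.1965 with an estimated correlation. At day 1 its median was 0.05. With 3 rats per treatment, day 4 does not settle chance. Chance with the choice of list allowed for, dividing immune cells and a response of duct cells to the water load stay open. So do dividing fibroblasts or endothelial cells, whose markers had medians of 1.37 and 0.81.

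The 355 genes that changed over days in control rats exceeded every other split drawn, 1 of 100 being the real one and 153 genes the highest other. This argues against chance for that fit. Without day 1 control 1 the count was 43, under that highest other, and no splits were drawn for that fit. With a proximal tubule score as a covariate 95.2% were called again, which argues against proximal tubule contamination as their source. With a fibroblast and pericyte score 11.3% were called again; the median size of their difference from day 1 to day 4 went from 2.32 to 2.17 log2 units and its median SE from 0.54 to 0.68, so calls ended with a wider spread while most of the difference stayed. In water-loaded rats, a comparison without day 1 control 1, 91.9% of the 347 genes called from day 1 to day 4 went the same way (89.6% to 91.6% without any 1 library) against 61.5% of all genes, which counts against fibroblasts or smooth muscle in that library as the whole source, but the median difference of 1.43 log2 units fell to 1.30 without day 1 water-loaded 2, under the bound of 0.5 of the 2.72 in control rats, so this stays open, as does a part in genes such as Eln, Vim, Tagln and Col1a1, which went the other way there. Cnn1, Myh11 and Des went the same way there, at -2.38, -1.27 and -1.13 log2 units against -12.86, -14.92 and -18.02 in control rats. Between the day 2 water-loaded libraries numbered 3 and 4 and those numbered 1 and 2, 74.4% of these genes had the same sign, against 57% of all genes, but their median difference there was 0.36 log2 units; a batch of libraries and the days of DDAVP cannot be told apart, since each day was a separate set of libraries.

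DESeq2 called 1126 genes at day 1 where edgeR called 0. Fitted on day 1 alone, the real split gave 141 DESeq2 calls and 5 of the 10 splits gave as many, the highest other being 453; so few splits cannot reach a share under 0.05. Without day 1 control 1 and water-loaded 2, the libraries with the fewest genes, 501 calls were left (44.5%), and without the other 8 pairs 853 to 1813. The count fell below 1126 only in pairs with control 1, to 853 with water-loaded 1 and 1064 with water-loaded 3. It rose to 1412 and 1654 without water-loaded 2 and control 2 or 3. Control 1, more than water-loaded 2, may therefore be a source of many of the calls. In 44.8% of the called genes the groups overlapped in CPM, which leaves open how far single outlying libraries made the calls.

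For the average over days, 1 of 100 splits within days, the real one with 23 genes, gave as many calls, and the highest other gave 8. This argues against chance for that fit. With the number as a block fewer than 8 genes were called over the average. Without any 1 library the count was 6 to 37, and over all alternatives 4 to 708. No splits were drawn for those fits. At day 2 the real split gave 0 genes, so all 35 gave at least as many and the count decides nothing; the split by libraries numbered 1 and 2 against 3 and 4 gave 74 genes, which points to a structure of the samples, and with the number as a block the real split gave 0. For the difference between days the real split gave 0 genes too, so that all 100 gave at least as many, the highest other 9, decides nothing either. At days 1 and 4 the real split gave 0 genes as well, so 10 of 10 splits had to give at least as many and the count decides nothing. The highest others gave 33 and 0, and 10 splits would also be too few for a share under 0.05.

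The principal cell markers averaged 9.26 log2 CPM in day 2 control 1 against 9.60 to 9.61 in the other 3 control rats, a library far from the rest of its group, 1 of 64 such sets of 4 tested, where chance gives about 1 in 20. Several lists differed in their effect between days by camera with the preset correlation, and none of these differences held with an estimated correlation (adjusted p from 0.266 to 0.754). From day 1 to day 2 the effect moved by a median of -4.51 in proximal tubule markers, -3.72 in thick ascending limb markers, 2.44 in cell cycle genes, 0.472 in oxidative phosphorylation, 0.36 in cytoplasmic ribosomal proteins and 0.667 in the proteasome. From day 1 to day 4 it moved by 4.09 in fibroblast and pericyte markers, 2.41 in cell cycle genes and 0.795 in the proteasome. From day 2 to day 4 it moved by 2.74 in proximal tubule markers, -0.309 in oxidative phosphorylation, -0.922 in mitochondrially encoded genes and -0.393 in cytoplasmic ribosomal proteins. Single libraries weigh on some of these values. The proximal tubule markers averaged 7.50 log2 CPM in day 1 water-loaded 2, against -0.37 and 0.88 in day 1 water-loaded 1 and 3. They averaged 4.90 in day 2 control 1, against 0.08 to 1.44 in the other day 2 control rats. The fibroblast and pericyte markers averaged 3.99 in day 1 control 1, against -0.36 and -0.40 in day 1 control 2 and 3. Slc2a4 stood in opposite directions at 2 days in every rat, with 0.0195 CPM in water-loaded and 56.2 CPM in control rats at day 1 (fitted log2 difference -11.26, or -8.99 without day 1 control 1) and 4.58 and 0.252 CPM at day 4. By edgeR the effect of Slc2a4 was not called as differing between these 2 days (adjusted p = 0.2345).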

How the results depend on the processing

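Setting 2 libraries aside, the fibroblast and pericyte score, the term for the day 2 libraries numbered 3 and 4, the filter of 50 CPM and the filter of 5 CPM with 2 libraries aside were chosen after the data were seen. Over 67 named results of single genes, 2248 of 2431 values under alternatives kept their direction and side of the threshold, 72 lost a call and 50 gained one. In 61 a gene called in neither fit changed sign, Aqp4 among them, and 0 calls turned. Over 26 list results, 606 of 702 values did, 95 lost the call and 1 more lost it with its median near 0 and still positive. That 1 was the proximal tubule list at day 1 with its own score as a covariate, a loss fixed in advance. The proximal tubule list at day 2 lost its call with that score in the same way. The cause of each change was not tested.

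DESeq2 called 1126, 77, 319, 708, 193 and 1589 genes for day 1, day 2, day 4, the average, the difference between days and the control days, against 0, 0, 0, 23, 0 and 355. limma-voom called 6 at day 2, 8 at day 4, 102 over the average and 2 for the difference. On log2(FPKM + 1) there were 3 at day 1 and 1 at day 4, without a filter 2 and 8, and with 0.1 in place of 1, 13 over the average and 1 for the difference. A filter of 5 CPM gave 35 over the average and 562 over control days; one of 50 CPM gave 12 at day 2 and 1 at day 4; 5 CPM with 2 libraries aside gave 1 and 4. An adjusted p threshold of 0.1 gave 94 over the average and 982 over control days. The proximal tubule score gave 628 over control days, the fibroblast and pericyte score 47, and 2 libraries aside 185. The number of detected genes as a covariate gave 4 over the average, with Aqp2 at -1.04.

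The replicate block gave 5 genes over the average and Aqp2 at -1.08 (adjusted p = 0.185). These 5 were all among the 23, and the other calls of the average were lost. With the block 3, 10, 6 and 5 lists were called at days 1, 2 and 4 and over the average, 1 of those at day 4 not being among the 5 called without it. At days 1 and 4 same-numbered libraries did not correlate more than other pairs, which with 3 rats per treatment does not settle whether rats were paired. The control days were not run with a block, since equal numbers there are different rats. With an estimated correlation 0, 1, 0 and 0 lists were called at day 1, day 2, day 4 and over the average, and by fry 0, 2, 0 and 4. With the proximal tubule score 5 and 8 lists were called at days 1 and 4. The proximal tubule list at day 1 then stood at 0.12 (adjusted p = 0.896 by camera). The score is the mean of that same list, so this loss was fixed in advance and says nothing about the list. With 2 libraries aside 1 list was called at day 1.

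Without 1 library at a time, Aqp2 ranged from -1.16 to -0.98. Genes called ranged from 0 to 9 at day 1, 0 to 0 at days 2 and 4, 6 to 37 over the average, 0 to 3 for the difference and 43 to 563 over control days. Lists called ranged from 1 to 7, 8 to 14, 4 to 9 and 5 to 9 at days 1, 2 and 4 and over the average.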

Other observations

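The gene families below were looked at after their values were seen. Of 9 alpha and beta tubulin genes with at least 10 CPM, all 9 had a positive log2 difference over the average (median 0.65), 5 with an unadjusted p under 0.05, and Tuba4a was called. At day 2 the median was 1.16, with 8 positive; Tuba1b stood at 1.22, Tuba1c at 1.16 and Tubb2a at 1.19. At day 1 the median was 0.03 and at day 4 0.70. Reads shared between near-identical tubulin genes and their copies leave these values uncertain.

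Of the genes called over the average at low levels, 4 are given here, chosen after their values were seen. Kif22 had means of 16.76 CPM in water-loaded and 0.896 CPM in control rats, Mad2l1 7.22 and 0.958 CPM, Knstrn 14.83 and 0.76 CPM, and Uhrf1 4.96 and 0.0964 CPM. Among the EGF receptor and MAPK feedback genes, Phlda1 stood at -1.54 (SE 0.35) and Spry2, a feedback inhibitor of receptor tyrosine kinases, at -1.34 (SE 0.41), both below 0.05 when adjusted over the list alone and not over all genes. Among the tubule injury genes, Lcn2 stood at 4.77 (SE 1.08), Krt19 at 3.15 (SE 0.83) and Tnfrsf12a at -0.99 (SE 0.24), again only when adjusted over the list alone. Neither list was called.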
